A study of Mus musculus with 4 samples.

How the data were processed

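RNA was measured in 4 clones of mouse embryonic stem cells, 2 with Gcn5 (WT) and 2 without (KO). Per the labels' protocols, 2 Gcn5 flox/flox founder lines, 4 and 6, were transfected transiently with a vector for a GFP-Cre fusion and sorted at 72 hours, and from each line a WT clone was picked from the GFP-negative cells and a KO clone, with exons 3 to 18 of Gcn5 removed, from the GFP-positive cells. The Gcn5flox lines were grown on feeder fibroblasts with 15% serum and 1000 U/mL of LIF. Whether feeder cells were removed before RNA was taken is not given in the sources used here. Total RNA was isolated, 1 µg of it was spiked with 2 µL of ERCC control RNA diluted 100-fold, mix 1 or mix 2, and ribosomal RNA was removed in a stranded library kit. The labels do not say which clone received which mix. The spike-in was added per mass of RNA.

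The deposited values are spike-in normalized FPKM, per the file headers, with 1 value per gene and library. Bowtie 0.12.8, TopHat2 2.0.9, affy, HTSeq and edgeR are named in the submitters' processing notes, without their roles, and so is the genome build, mm9. How the spike-ins were used to scale the FPKM is not given in the sources used here. Each file held 23376 entries, 92 of them spike-ins. In each, 25 entries had no partner of the same name in the other files, as gene names stood as dates in some files and as spreadsheet day numbers in others, and these were left out, which left 23259 genes. Depth is unknown: low values moved in steps, but FPKM steps depend on gene length and did not give counts, so no counting interval is given. Genes without signal shared a value in each library, between 0.00937 and 0.0107 FPKM.

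Values were taken as log2(FPKM + 1), which understates the change of low genes, and genes with a mean of at least 1 FPKM over the 4 libraries were tested, 11932 in all. KO was tested against WT with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists fixed before the data were examined, 38 of them, were tested with camera at a preset correlation of 0.01, where at least 5 members were tested, which held for 32 lists. A list call compares the t values of its members, each a log2 change over its SE, with those of all other tested genes. It is therefore relative to other genes but is not a distance from the median gene. Where most genes are lower in KO, members with a larger SE have t values nearer 0. A list of such members can be called upward without lying above the median gene. The same lists were tested with an estimated correlation and with fry, which compares no list with other genes. After the data were seen, lists were also placed among 10000 random lists matched on mean expression in 60 bins, from which the list's own members were not left out. The lists with fewer tested members were primitive streak and mesoderm (4), 2-cell-like genes (2), hematopoietic and immune genes (3), Hox genes (0), mitochondrially encoded genes (0) and X and Y marker genes (3), and have no list test.

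The replicate number is the founder line, per the names of the clones in the labels, so WT and KO of 1 number come from the same line and the numbers pair the samples. Across genes, the deviations of WT and KO of 1 number correlated at r = 0.70, and log2 values correlated at 0.995 between WT and KO of line 4 and at 0.99 in line 6, against 0.975 between the WT clones and 0.979 between the KO clones. Genes are not independent replicates. The fit without this block was chosen before the data were examined, with the blocked fit as an alternative. On the deposited scale the blocked fit gave an infinite prior df, which means that all genes of a given level received the same spread, whatever the difference between the lines. The prior df was 16.4 without the block and 4.54 with the block on values centred on each library's median. For this reason fits with a robust spread were added after the data were seen. Each group holds 2 clones from separate founder lines. P-values of the gene test without the block rest in part on the spread between these clones, which includes the difference between the lines. With the prior df of 16.4, most of the weight went to the spread shared by genes of like level. Those of the blocked fit as deposited rest on the spread of the gene's level. Those of camera at the preset correlation rest on the spread across genes.

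The named genes follow a rule set before the data were examined. It takes Kat2a, Kat2b, the Myc genes, U2af1 and Srsf3, up to 12 genes per direction past the test and moved alike in both lines, filled with genes of the lowest p that changed by at least 1 on the log2 scale in both lines, without microRNA and other short RNA entries, pseudogenes and gene models without a name, and up to 4 members by lowest p of each list past the list test, and up to 2 of each other list. After the data were seen this was narrowed to the first 2 members of each list past the list test and none of the others. No gene met the part of the rule for opposite changes in the lines. Genes of the stretches on chromosomes 5 and 12, the imprinted genes and the genes that differed between founder lines were chosen after their values were seen, except where the rule names them. Neighbouring genes were taken from the RefSeq annotation of GRCm38.p6, in which 20682 of the 23259 names were found. It is not the authors' build, so it gave only the order of genes.

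The gene test was tested on simulated values for 11932 genes. Without the block it recovered 0% of 100 genes changed by 1 on the log2 scale and 95% of 100 genes changed by 2. With the block it recovered 85% and 100%, and called 10 unchanged genes. The list test recovered the shifted list in both fits and called 0 others. The simulated noise was independent between genes and had the spread of the blocked fit. Members of real lists were correlated, with an estimate of 0.776 for ribosomal proteins, so these rates may not hold for the data. Alternatives covered the pseudocount (0.1), the filter (none, or a mean of at least 5 FPKM), centring, quantile normalization, the block, the variance trend and leaving out each library. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 drew the figures.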

Results

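Gcn5 (Kat2a) is a histone acetyltransferase of the SAGA and ATAC coactivator complexes. Its transcript and all others were measured by RNA sequencing of total RNA in 2 WT and 2 KO clones of mouse embryonic stem cells, to see which expression levels changed in KO. Replicate 1 of each genotype came from founder line 4 and replicate 2 from founder line 6. In WT replicates 1 and 2, 12174 and 12002 genes reached 1 FPKM, and in KO replicates 1 and 2, 11562 and 11769 did. The summed FPKM of all genes was 757931 and 680168 in the WT replicates and 520491 and 538257 in the KO replicates. The deposited values are FPKM scaled to spike-ins, and the depth behind them is unknown.

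Kat2a was lower in both KO clones. It was listed at 38.7 and 34.4 FPKM in WT replicates 1 and 2, a mean of 36.6 ± 3.04 (SD, n = 2), and at 11.5 FPKM in each KO replicate, a mean of 11.5 ± 0.0324 (SD, n = 2), a KO/WT ratio of 0.315. The log2 fold change was -1.58 (SE 0.23, limma adjusted p = 0.0112), lower in 2 of 2 lines. Per the labels' protocols, quantitative RT-PCR and immunoblots did not detect Gcn5 in the KO clones. The deletion removes exons 3 to 18, and the files give 1 value per gene, so reads from the remaining exons cannot be separated from reads of the whole transcript. The call ended without KO replicate 1 or KO replicate 2, without a filter on low values, on values centred on each library's median and with quantile normalization, at log2 fold changes of -1.25 to -1.59 and adjusted p of 0.426 to 1.00. With the founder line as a block, the adjusted p was 8.19e-11 as deposited and 0.0469 on centred values. Kat2b, the paralog of Gcn5, was listed at 20.0 ± 0.726 FPKM in WT and 15.9 ± 4.39 FPKM in KO (SD, n = 2) and did not pass the test (log2 fold change -0.33, limma adjusted p = 0.445). The median gene fell by nearly as much, and relative to it Kat2b lay at -0.018.

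**Figure D1:**
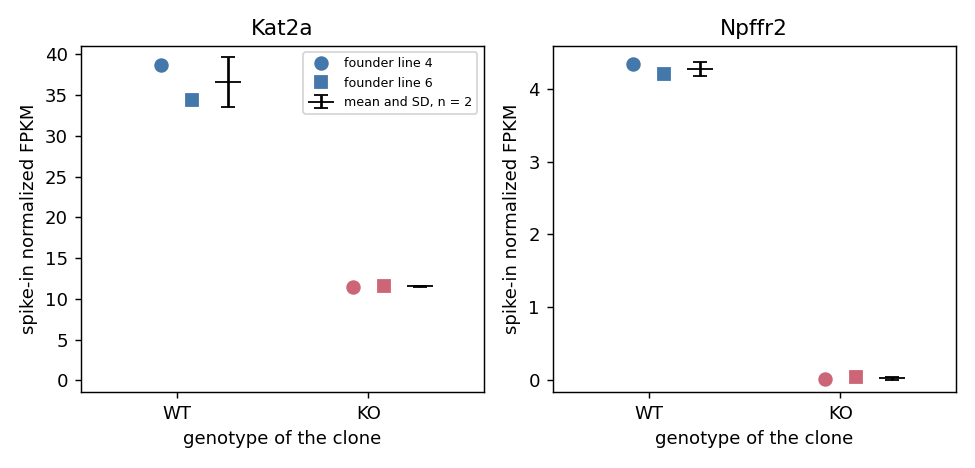
Spike-in normalized FPKM of Kat2a and Npffr2 in each clone, by genotype; circles are founder line 4, squares founder line 6, and bars show the mean and SD (n = 2). Kat2a stood at 38.7 and 34.4 in WT and 11.5 in both KO clones, and Npffr2 at 4.34 and 4.20 in WT and under 0.1 in KO.

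Most transcripts were listed at lower values in KO than in the WT clone of the same line, and by more in line 4. The median log2 difference was -0.44 in line 4 and -0.19 in line 6, which is a ratio of KO + 1 to WT + 1 FPKM of 0.735 and 0.88. With a pseudocount of 0.1 FPKM in place of 1 this ratio was 0.708 and 0.866. In line 4, 97.6% of tested genes were lower in KO, in line 6 87.7%, and 86.3% were lower in both. There is 1 pair of clones per line, so the shift was described and not tested. Over all 4 libraries the median log2 fold change was -0.32, and centring takes it away, so changes of gene groups are given relative to the median gene. The median of 32 spike-ins lay at -0.16 on the log2 scale from the ratio of their mix class in line 4 and at -0.020 in line 6. Each spike-in was placed in the class of the nearest ratio, which keeps these distances small.

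**Figure D2:**
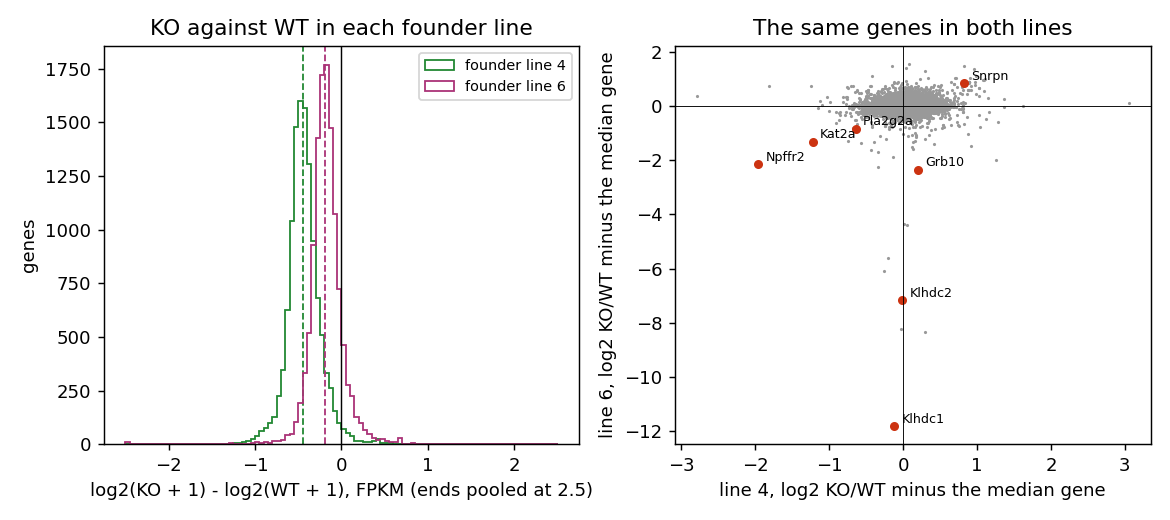
Left, number of genes by log2(KO + 1) - log2(WT + 1) in each founder line, with dashed lines at the medians of -0.44 and -0.19. Right, the log2 change of each gene minus the median gene in line 6 against line 4; Kat2a and Npffr2 are low in both lines, while Klhdc1, Klhdc2 and Grb10 are low in line 6.

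Besides Kat2a, 1 gene passed the test between KO and WT. Npffr2, which encodes a receptor for neuropeptide FF, was listed at 4.34 and 4.20 FPKM in the WT replicates and at 0.00880 and 0.0351 FPKM in the KO replicates, close to the value of genes without signal (log2 fold change -2.37, SE 0.25, limma adjusted p = 0.000175). This call, too, ended without KO replicate 1 or KO replicate 2, without the filter and with either rescaling. It passed with the block (limma adjusted p = 1.58e-31, and 0.0469 on centred values). The log2 fold change of Npffr2 stayed at -2.39 to -2.35 without single libraries and was -2.06 on centred values. Its neighbours on chromosome 5, Gm7056 and Adamts3, were also low in both KO clones. In all, 0 genes were higher and 2 lower in KO, against 10 higher and 651 lower at an unadjusted p under 0.05, and 60 higher and 24 lower on centred values, where limma called 0. Pla2g2a, a secreted phospholipase, was also lower by at least 1 on the log2 scale in both lines, as were the microRNA entries Mir5107 and Mir491, which the naming rule leaves out and which were chosen after their values were seen (adjusted p = 0.19 and 0.445; 1.06e-08 and 4.00e-06 with the block; 0.261 and 0.535 with the block on centred values). Pla2g2a stood at 2.60 ± 1.06 FPKM in WT and 0.718 ± 0.462 FPKM in KO (SD, n = 2) and did not pass (log2 fold change -1.06, adjusted p = 0.445; 2.37e-05 with the block; 0.32 with the block on centred values). The block called 95 genes, 4 higher and 91 lower, of which 42 were short RNA entries and 26 had changes over 1 log2 unit apart between the lines, since that fit gave each gene the spread of its level. With a robust spread the block called 91, with 78 of the same genes. On centred values the block called 33 genes, 31 higher and 2 lower, of which 27 were short RNA entries, and with a robust spread it called 2, Kat2a and Npffr2. Leaving out WT replicate 1 or WT replicate 2 gave 20 and 133 genes, and leaving out KO replicate 1 or KO replicate 2 gave 0. With 1 library left out and no block, 1 founder line stands for WT or KO alone, so all values without a library also hold the difference between the lines.

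The Myc genes and the splicing factors U2af1 and Srsf3 did not pass the test. Myc was listed at 2.63 and 8.91 FPKM in the WT replicates and 2.08 and 7.96 FPKM in the KO replicates, so the lines differed by more than the genotypes (log2 fold change -0.19, limma adjusted p = 0.718). Mycn, the more abundant family member, had a log2 fold change of -0.45 (adjusted p = 0.445) and Mycl1 one of -0.19 (adjusted p = 0.606). U2af1, a subunit of the factor that recognises the 3' splice site, had a log2 fold change of -0.42 and Srsf3, an SR protein, one of -0.34 (adjusted p = 0.445 for both). On centred values Myc and Mycl1 were above 0, at 0.12 each, and with quantile normalization Myc, Mycl1 and Srsf3 were, at 0.074, 0.095 and 0.042. Relative to the median gene Mycn lay at -0.14, U2af1 at -0.10 and Srsf3 at -0.019.

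The log2 changes of the 2 lines correlated weakly across genes, which are not independent replicates, with Pearson's r = 0.11 and Spearman's rho = 0.11. By at least 1.5-fold, 1926 genes were lower in line 4 and 179 in line 6, with 45 in both, where independent lists would share 28.9. For higher genes the counts were 14, 61 and 3, against 0.0716. Relative to the median gene of each line, 52 genes were higher in both lines against 1.45 by chance, 7 were lower in both against 0.497, and 15 moved in opposite directions. Many of these were microRNA entries with shared or identical values: without short RNA entries, and with identical entries counted once, 8 genes were higher in both against 0.389 and 6 lower against 0.2, and 0 were higher as deposited. Npffr2, Kat2a and Pla2g2a were among the genes lower in both.

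Transcripts of fibroblasts lay above the median gene in KO, and more so in line 6. Of the 34 tested members of the feeder fibroblast list, 31 lay above the median gene, 24 of them in both lines (camera adjusted p = 8.56e-17; 3.83e-10 with the block; adjusted p = 0.925 with an estimated correlation). The list's median relative to the median gene was 0.09 in line 4 and 0.43 in line 6. As deposited, its median was -0.35 in line 4 and 0.25 in line 6. No single member passed the test over all genes, with 0 adjusted over the list alone. The 2 members with the lowest p, which favours members that fell, lay below the median gene over the 4 libraries, unlike most of the list. Fstl1 had a log2 fold change of -0.50 and Fn1, which encodes fibronectin, one of -0.47 (limma adjusted p = 0.445 for both). The lines were grown on feeder fibroblasts. The list kept its call without each single library. The cytoskeleton, adhesion and EMT list had 20 of 31 members above the median gene (camera adjusted p = 0.00328, 0.0295 with the block and 0.962 with an estimated correlation), with 0 past adjusted over the list alone. Actb, cytoplasmic actin, and Epcam, an epithelial adhesion protein, had the lowest p and lay below the median gene. Their log2 fold changes were -0.58 and -0.42, or -0.26 and -0.11 relative to the median gene. Actb passed with the block (adjusted p = 0.0478) and not with the block on centred values (0.832). Without WT replicate 1 or KO replicate 2 the list lay below the median gene, at -0.042 and -0.052 (adjusted p = 0.686 and 0.868).

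Among lists of differentiated cells, the trophectoderm list had 7 of 11 members above the median gene (adjusted p = 0.00499; 0.221 with the block; adjusted p = 0.925 with an estimated correlation), at 0.22 in line 4 and -0.10 in line 6, so the lines went in opposite directions. Its members with the lowest p, Phlda2 and H19, are also imprinted and lay below the median gene over the 4 libraries, with log2 fold changes of -1.18 and -0.69 (limma adjusted p = 0.445 for both). Phlda2 was the 1 member past adjusted over the list alone. It passed with the block (1.32e-05) and not with the block on centred values (0.799), with the lines at -0.40 and -1.34 relative to the median gene. The list's call ended without WT replicate 1, WT replicate 2 or KO replicate 1 (adjusted p of 0.126 to 0.987). The endoderm list (adjusted p = 0.733) and the ectoderm and neural list (0.776) did not pass; their medians lay below the median gene while the test pointed upward. Genes of the formative and primed epiblast, the state that follows naive pluripotency, had 13 of 17 members above the median gene (adjusted p = 1.83e-05; 0.00835 with the block; adjusted p = 0.962 with an estimated correlation), at 0.35 in line 4 and 0.03 in line 6, with 0 past adjusted over the list alone. Etv4 and Fgf15 had the lowest p, at log2 fold changes of -0.35 each, and lay slightly below the median gene, at -0.033 and -0.029 relative to it. Without WT replicate 1 the list passed in the opposite direction, at -0.41 (adjusted p = 3.28e-05; adjusted p = 0.731 with an estimated correlation), and without KO replicate 2 it lay at -0.24 (0.297). The list differed by 1.04 between the founder lines, which enters these values and exceeds them.

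Pluripotency genes lay below the median gene in KO. Of 40 tested members, 34 were below it (adjusted p = 0.0144; 0.0231 with the block; adjusted p = 0.962 with an estimated correlation), with relative medians of -0.09 in line 4 and -0.06 in line 6, and 0 past the test adjusted over the list alone. Nr0b1 and Zfp296, both transcription factors of naive stem cells, had log2 fold changes of -0.64 and -0.65 (adjusted p = 0.445). The feeder fibroblast list lay above the median gene in both lines, at 0.09 and 0.43, so a changed share of feeder cells was not separated from a change in the stem cells. The list's call ended without WT replicate 1, WT replicate 2 or KO replicate 1 (adjusted p of 0.0841 to 0.62). The integrated stress response list had 19 of 21 members below the median gene (adjusted p = 0.000739; 0.00458 with the block; adjusted p = 0.962 with an estimated correlation), at -0.20 in line 4 and -0.02 in line 6, with 1 past adjusted over the list alone; Cth, an enzyme of cysteine synthesis, had a log2 fold change of -0.85 (adjusted p = 0.445; 0.00419 with the block; 0.824 with the block on centred values) and Chac1, which degrades glutathione, one of -0.62. Without WT replicate 1 or KO replicate 1 the list did not pass (adjusted p = 0.351 and 0.225).

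All 48 tested ribosomal protein genes lay below the median gene (adjusted p = 5.3e-12; 2.85e-06 with the block; adjusted p = 0.962 with an estimated correlation), with relative medians of -0.11 in line 4 and -0.18 in line 6. Tested against 0 and not against the median gene, 43 passed adjusted over the list alone and 0 over all genes. Those 43 therefore also hold the shift of most genes. With the block 4 passed over all genes, and with the block on centred values 0. Rps24 and Rpl8 had log2 fold changes of -0.61 and -0.60 (adjusted p = 0.445; 0.0263 and 0.0301 with the block). With the block on centred values they lay at -0.31 and -0.29 and did not pass (adjusted p = 0.832 for both). The call held without each single library. With quantile normalization the list lay 0.032 above the median gene (adjusted p = 0.527). The oxidative phosphorylation list had 27 of 34 members below the median gene (adjusted p = 0.00834; 0.16 with the block), the core spliceosome list 36 of 54 (0.0198; 0.215) and the list of nucleolar Myc targets 33 of 46 (0.0144; 0.118); the adjusted p was 0.962 for each with an estimated correlation, and 0 members passed adjusted over the list alone. With the block on centred values these 3 lists passed (0.0107, 0.0217 and 0.0109; adjusted p = 0.772 for each with an estimated correlation). The respiratory list lost its call when any 1 of the 4 libraries was left out (adjusted p of 0.0655 to 0.138). Without WT replicate 2 or KO replicate 1 the nucleolar list lay above the median gene, at 0.074 and 0.051, and so did the spliceosome list, at 0.010 and 0.021. With quantile normalization all 3 lay above it, at 0.018 for the respiratory and nucleolar lists and 0.013 for the spliceosome. Ndufs1 and Atp5b of the respiratory chain had log2 fold changes of -0.56 and -0.44, the spliceosome components Snrpd3 and Sf3b1 -0.53 and -0.61, and Hspe1 and Ncl, a chaperone and a nucleolar protein, -0.57 and -0.68 (limma adjusted p = 0.445 for all). In lines 4 and 6 Sf3b1 lay at -0.94 and -0.28 and Ncl at -1.18 and -0.19. Ncl passed with the block and a robust spread (adjusted p = 0.0387) and not with the block on centred values (0.832). Without single libraries Sf3b1 ran from -1.02 to -0.20 and Ncl from -1.03 to -0.33.

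**Figure D3:**
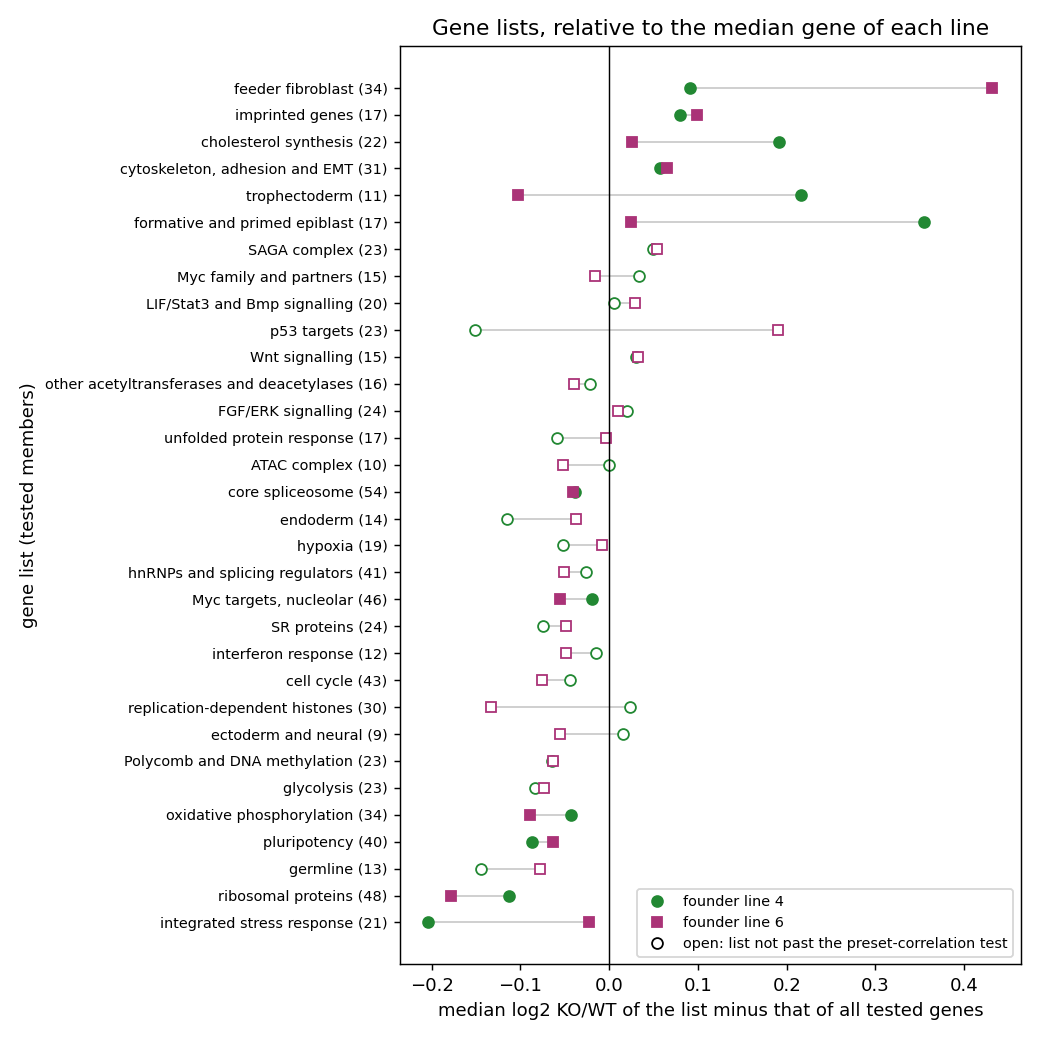
Median log2 KO/WT of each gene list minus that of all tested genes, in founder line 4 (circles) and line 6 (squares), with the number of tested members; filled symbols mark the 12 lists past the test at the preset correlation. The feeder fibroblast list lies at 0.09 and 0.43, and the ribosomal protein list lies at -0.11 and -0.18.

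Cholesterol synthesis genes had 21 of 22 members above the median gene (adjusted p = 0.0144; 0.0552 with the block; 0.00329 with the block on centred values; adjusted p = 0.925 with an estimated correlation), at 0.19 in line 4 and 0.03 in line 6, with 0 past adjusted over the list alone. Its members with the lowest p, Fdft1 and Insig1, had log2 fold changes of -0.33 and -0.31. Relative to the median gene they lay at -0.017 and 0.0049, so Fdft1 was the 1 member below it. The list's call ended without WT replicate 1 or KO replicate 1 (adjusted p = 0.328 and 0.62). Imprinted genes had 9 of 17 members above the median gene (adjusted p = 0.0144; 0.938 with the block; adjusted p = 0.925 with an estimated correlation), a relative median of 0.14 and a relative mean of 0.00349, with 1 past adjusted over the list alone. The call ended without WT replicate 1, WT replicate 2 or KO replicate 1 (adjusted p of 0.164 to 0.686). Phlda2 and Grb10, a growth factor receptor adaptor, had the lowest p and lay below the median gene. Grb10 stood at 61.1 FPKM in WT replicate 2 and between 8.56 and 10.4 FPKM in the other libraries (log2 fold change -1.40, adjusted p = 0.445; 7.9e-08 with the block, 0.35 with the block and a robust spread and 0.847 with the block on centred values). In all, 12 lists passed at the preset correlation, 6 passed with the block, and 0 passed with an estimated correlation or with fry. On centred values 8 passed, and 14 with the block on centred values, among them all of the 12 but trophectoderm (0.0798) and imprinted genes (0.197). With an estimated correlation 0 passed in these fits (smallest adjusted p = 0.73 and 0.772).

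Of the 12 lists, the feeder fibroblast and integrated stress response lists kept their calls with a pseudocount of 0.1, without a filter, at a mean of at least 5 FPKM, on centred values and with quantile normalization, and ribosomal proteins lost theirs with quantile normalization alone. Pluripotency lost its call with a pseudocount of 0.1 (adjusted p = 0.227), without a filter (0.0582), at a mean of at least 5 FPKM (0.0779) and with quantile normalization (0.165). Formative and primed epiblast lost it on centred values (0.115) and with quantile normalization (0.298), trophectoderm in the same cases (0.0587 and 0.165), cytoskeleton and adhesion without a filter (0.79) and on centred values (0.115), and cholesterol synthesis without a filter (0.555). Imprinted genes lost it without a filter (0.0682), at a mean of at least 5 FPKM (0.0779), on centred values (0.144) and with quantile normalization (0.236). Oxidative phosphorylation, nucleolar Myc targets and the core spliceosome lost theirs with a pseudocount of 0.1 (0.0915, 0.227 and 0.227), at a mean of at least 5 FPKM (0.0992, 0.147 and 0.28) and with quantile normalization (0.872 each).

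Placed among random lists of like expression, which describes these libraries and is no test, some lists past the test did not stand apart in 1 line or in both. The random lists could draw the list's own members, which pulls a percentile towards the middle. The pull is strongest where a list makes up much of its expression level, as abundant ribosomal protein genes may. A middle percentile of that list therefore does not show that it moved like other genes. Ribosomal proteins stood at percentiles 27.9 in line 4 and 8.54 in line 6, oxidative phosphorylation at 47.2 and 10.3, and pluripotency at 1.01 and 17.1. The integrated stress response stood at 0 and 63.6, the core spliceosome at 41.8 and 79.5 and nucleolar Myc targets at 82.9 and 65.8, so the latter lay above the middle of such lists in both lines. Of the lists above the median gene, feeder fibroblast stood at 99.98 and 100, cytoskeleton and adhesion at 99.8 and 100, imprinted genes at 98.8 and 99.8, cholesterol synthesis at 100 and 96.9, formative and primed epiblast at 100 and 69.2 and trophectoderm at 99.98 and 1.75.

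The SAGA complex list did not pass (adjusted p = 0.63): its relative median was 0.05, its relative mean -0.03, and Kat2a was the single member past the test. The ATAC complex list (0.375) and other acetyltransferases and deacetylases (0.449) did not pass. All 3 passed downward without a filter on low values (0.0135, 0.00414 and 0.00464; adjusted p = 0.66 for each with an estimated correlation). Of the splicing lists, SR proteins had 21 of 24 members below the median gene and an adjusted p of 0.0635, and hnRNPs and splicing regulators one of 0.118, and neither passed. SR proteins passed with the block on centred values (0.0214), without a filter (0.00219) and without WT replicate 1 or KO replicate 2 (0.0252 and 0.00422), and hnRNPs without a filter (0.00105) and without the same libraries (0.00129 and 0.00194). With an estimated correlation none of these calls held (adjusted p of 0.66 to 0.772). The Myc family and its partners gave an adjusted p of 0.737, the cell cycle list 0.0563, germline genes 0.107, the unfolded protein response 0.175, LIF/Stat3 and Bmp signalling 0.212, replication-dependent histones 0.412, Polycomb and DNA methylation genes 0.547, FGF/ERK signalling, Wnt signalling and glycolysis 0.604 each, p53 targets 0.837, hypoxia 0.881 and interferon response 0.993. Germline genes (0.0109), glycolysis (0.0124) and cell cycle (0.0323) passed downward with the block on centred values (adjusted p = 0.772 for each with an estimated correlation). Germline genes also passed downward with quantile normalization (0.00952; 0.000643 with the block) and without WT replicate 2 or KO replicate 1 (0.000463 and 0.00127), and cell cycle without a filter (8.7e-05); none of these calls held with an estimated correlation (adjusted p of 0.66 to 0.962). The unfolded protein response passed downward without a filter (0.00219) and without KO replicate 2 (0.0128), the interferon response upward without WT replicate 1 or KO replicate 2 (0.0339 and 0.0436), and p53 targets upward without WT replicate 1 (0.0099) and downward without WT replicate 2 (0.0421). Ectoderm and neural genes passed upward without a filter (0.0482). With an estimated correlation these calls were lost (adjusted p of 0.66 to 0.751). Glycolysis, hypoxia, histones and endoderm passed upward or downward depending on which library was left out, with medians of -0.38 to 0.26, -0.42 to 0.27, -0.35 to 0.25 and -0.26 to 0.39, and the medians of these 4 lists also differed between the founder lines. With an estimated correlation 0 lists passed without any 1 library (smallest adjusted p = 0.731). For histones, hypoxia and p53 targets the test pointed upward while median and mean lay below 0, for FGF/ERK and Wnt signalling the median alone lay below 0.

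Genes that neighbour Npffr2 in GRCm38.p6 were low together. Gm7056 was listed at 1.11 and 1.12 FPKM in the WT replicates and at 0.00920 and 0.00910 FPKM in the KO replicates, and Adamts3, a procollagen protease, at 0.549 and 0.683 FPKM in WT and 0.106 and 0.165 FPKM in KO. The next expressed genes on either side had KO/WT ratios of 0.667 and 1.29 (Gc) and 0.641 and 0.805 (Cox18) in lines 4 and 6. On chromosome 12, 8 neighbouring genes from Lrr1 to Nemf were high in WT replicate 2 alone: Klhdc1 stood at 4857 FPKM there against at most 1.57 FPKM in the other libraries, and Klhdc2 at 4956 FPKM against at most 37.5 FPKM. With the block Klhdc1 and Klhdc2 passed (adjusted p = 7.29e-169 and 1.15e-89), and with the block and a robust spread they did not (0.525 and 0.517), nor with the block on centred values (0.832 for both).

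**Figure D4:**
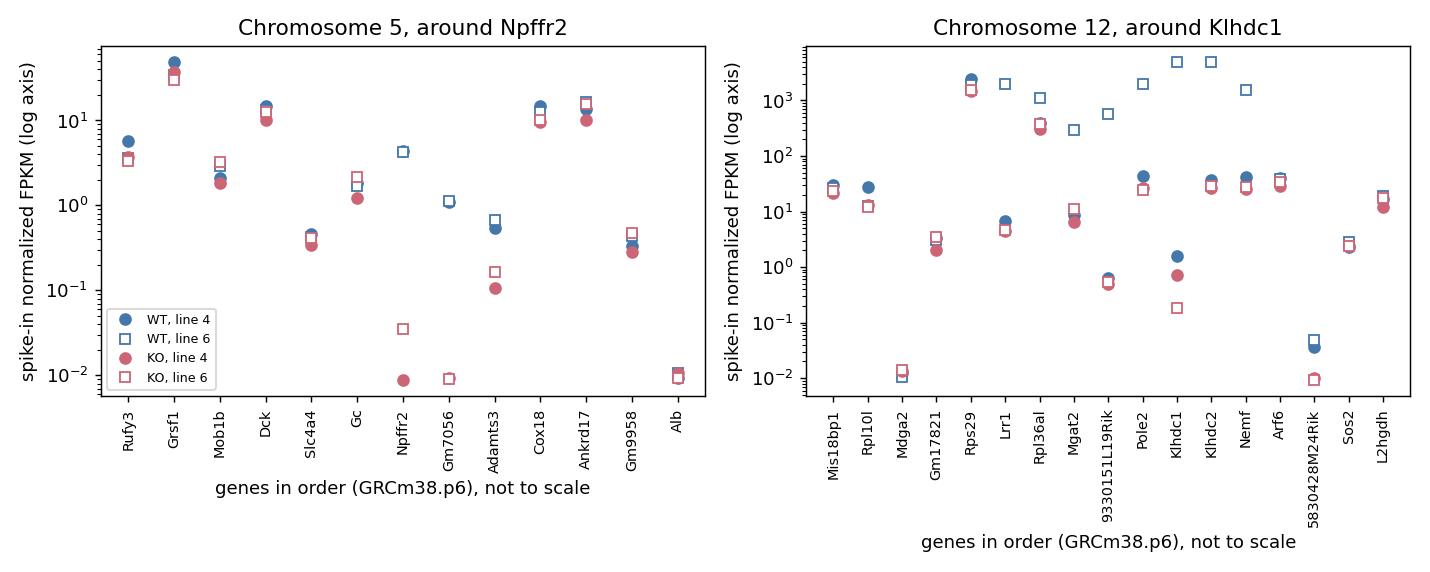
Spike-in normalized FPKM, on a log axis, of genes in chromosomal order around Npffr2 and around Klhdc1; blue is WT, red KO, filled circles line 4 and open squares line 6. Npffr2, Gm7056 and Adamts3 are low in both KO clones, and 8 genes from Lrr1 to Nemf are high in WT replicate 2 alone.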

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

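The tests in this part were chosen after the results were seen, as the count of other genes lost at the level of Npffr2 also rests on that gene's call. The feeder fibroblast list went in opposite directions in the lines as deposited, with a median log2 KO/WT of -0.35 in line 4 and 0.25 in line 6, and so did the p53 targets, at -0.60 and 0.0054; these differences were not tested. The spike-ins, which the gene and list tests leave out, differed between WT and KO. Each was placed in the mix class whose expected log2 ratio lay nearest its own mean log2 KO/WT over the lines. This favours class medians near the expected ratios by construction, but least for the class expected at -2, which has no other class near it. The class expected at -2 had a median log2 KO/WT of -2.15 in line 4 and -2.03 in line 6. The class expected at 1 had 0.85 and 1.01. By ratios this far apart the KO clones carried the other mix than the WT clones in both lines, and mix and genotype cannot be separated.

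Npffr2, Gm7056 and Adamts3 were low in both KO clones. Chance loss of low values would take other genes: of 2999 genes at 2 to 8 FPKM in both WT libraries, 1 was under 0.1 FPKM in both KO libraries, Npffr2 itself. Fewer feeder cells in KO would lower fibroblast transcripts, but the smaller relative median of the feeder list in the lines was 0.0914, above 0. Fn1, its most abundant member, was at 132.2 and 76.6 FPKM in WT and still at 64.2 and 81.6 FPKM in KO. In line 4 Fn1 lay below the median gene, at -0.59 relative to it, and in line 6 above it, at 0.28. What stays open is a change of the locus itself in KO, such as a deletion or silencing of the stretch; the lowest KO/WT ratio of Gc and Cox18 was 0.641, so the flanking genes kept most of their signal, and reads would be needed to tell these apart. The biological explanation the design gives, loss of Gcn5, stays open and untested, and the KO clones also share the exposure to Cre and the sort for GFP.

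The stretch on chromosome 12 was high in WT replicate 2 alone. A higher DNA copy number alone would raise the genes by like factors, but among genes of at least 2 FPKM elsewhere the highest factor was 103 times the lowest. Reads shared between Klhdc1 and Klhdc2 leave 6 other raised genes unexplained. An added transcript across the stretch in this clone remains a candidate explanation: 2 entries under 2 FPKM elsewhere were raised, and reads would be needed to see where it starts and ends. The rise over WT replicate 1 was uneven too, from 282 FPKM for Mgat2 to 4919 FPKM for Klhdc2. No biological explanation was tested, since the design names no group that sets this clone apart.

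Expression scaled to spike-ins was lower in KO in both lines. The offset of the spike-ins left after scaling, as the whole cause, leaves a shift of -0.28 in line 4 and -0.17 in line 6, beyond the SD of the spike-in residuals of 0.121 and 0.104. The mix classes were assigned from the same ratios, so the offset may be understated, and this comparison cannot exclude it. The amount of spike-in added per tube could move every gene of a clone by 1 factor, and the shift differed by 0.26 between the lines; the design has 1 tube per clone, and this cannot be told apart from a change in the amount of these transcripts per mass of RNA. Since the spike-in was added per mass of RNA, the shift does not measure RNA per cell, and loss of Gcn5 as a cause stays open and untested.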

How the results depend on the processing

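Of the alternatives below and above, those with a robust spread, without short RNA entries and with identical entries counted once, with the block and quantile normalization together, with an estimated correlation under other settings than the unblocked fit as deposited, and after subtraction of the spike-in residual were chosen after the data were seen. For single genes named, 585 values kept their direction and side of the threshold, 12 lost the threshold, 45 newly passed it and 26 changed direction. For lists these counts were 309, 92, 30 and 113. Where no reason is given, the cause was not tested. The replicate block with an infinite prior df, 1 pair of clones per line and an unknown depth limit these results. List calls that the block changed stand beside those lists above, and it changed no other list call. The fit without a variance trend called as many genes and lists as the fit with it.

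Against 2 genes between KO and WT, all lower, limma called 8 genes, all lower, at a mean of at least 5 FPKM, where fewer genes are tested, and 0 without a filter, on centred values and with quantile normalization. With the replicate block it called 95 genes, 4 higher and 91 lower, and with the block, without short RNA entries and with identical entries counted once, 52, of which 1 was higher and 51 lower. With the block and a robust spread it called 91, of which 3 were higher and 88 lower. With the block on centred values it called 33, of which 31 were higher, and with the block and quantile normalization 0. Leaving out single libraries gave 0 to 133 genes, all lower. Against 12 lists past the test, 8 passed with a pseudocount of 0.1, of which 6 were higher and 2 lower, 20 without a filter, among them lists with too few members above, 7 at a mean of at least 5 FPKM, 5 with quantile normalization with or without the block, 8 on centred values, 6 with the block and 14 with the block on centred values. No list, 0 in each case, passed with fry without the block, nor with an estimated correlation without the block, with the block, or with the block on centred values, nor with it under the other pseudocount, filters, rescalings and left-out libraries (smallest adjusted p = 0.66). Leaving out single libraries gave 9 to 17 lists.

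Kat2a kept its direction in each alternative. Its log2 fold change no longer passed without a filter (-1.58), on centred values (-1.28) and with quantile normalization with or without the block (-1.25), and ran from -1.67 to -1.50 without single libraries. The trophectoderm list, at 0.10, no longer passed with the block, on centred values with or without the block, or with an estimated correlation without the block, with the block, or with the block on centred values, all with that median, nor at 0.084 with quantile normalization with or without the block. The feeder fibroblast list, at 0.27, no longer passed with an estimated correlation without the block, with the block, or with the block on centred values. The ectoderm and neural list newly passed without a filter, at 0.19.

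The correlation of the KO change between the lines across genes was 0.055 with a pseudocount of 0.1, 0.29 without a filter, 0.107 at a mean of at least 5 FPKM, 0.108 on centred values and 0.070 with quantile normalization as Pearson's r. Spearman's rho, at 0.11, moved further, to 0.46 without a filter, and was 0.015 with a pseudocount of 0.1, 0.056 at a mean of at least 5 FPKM and 0.016 with quantile normalization. Genes lower by 1.5-fold in both lines numbered 150 with a pseudocount of 0.1, 20 at a mean of at least 5 FPKM, 7 on centred values and 8 with quantile normalization. Genes higher in both numbered 6 with a pseudocount of 0.1, 5 without a filter, 47 on centred values and 48 with quantile normalization. Without short RNA entries, and with identical entries counted once, 29 were lower and 0 higher in both.

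Changes of direction follow as medians relative to the median gene for lists and log2 fold changes for genes, and for lists the direction is that of the test. With quantile normalization, lists changed direction with SAGA complex at 0.025, endoderm at -0.0091, ectoderm and neural at -0.080, hnRNPs and splicing regulators at 0.0012, core spliceosome at 0.013 and ribosomal proteins at 0.032. Also changed were Wnt signalling at 0.026, glycolysis at 0.023, oxidative phosphorylation at 0.018 and hypoxia at -0.033. The genes were Myc at 0.074, Mycl1 at 0.095, Srsf3 at 0.042, Etv4 at 0.00081, Atp5b at 0.071 and Fdft1 at 0.018. Further genes were Insig1 at 0.034. With the replicate block and quantile normalization the same values hold for these lists and genes except Wnt signalling, which kept its direction, and nucleolar Myc targets changed at 0.018 and the unfolded protein response at -0.012.

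On centred values endoderm at -0.039, Wnt signalling at -0.0038, p53 targets at -0.0033, replication-dependent histones at -0.061, hypoxia at -0.040, Myc at 0.12 and Mycl1 at 0.12 changed direction. With the replicate block and centring, with or without an estimated correlation, lists changed with SAGA complex at 0.051, endoderm at -0.039, ectoderm and neural at -0.061, p53 targets at -0.0033, replication-dependent histones at -0.061 and hypoxia at -0.040. Myc and Mycl1 lay at 0.12 there too, and also with a robust spread. With the replicate block alone, and with its estimated correlation, endoderm at -0.039, p53 targets at -0.0033, replication-dependent histones at -0.061 and hypoxia at -0.040 changed direction. Without a filter on low values the lists were LIF/Stat3 and Bmp signalling at -0.092, germline at -0.094, Myc family and partners at -0.085, FGF/ERK signalling at -0.033, p53 targets at -0.100 and replication-dependent histones at -0.16. Also changed were cholesterol synthesis at 0.015, hypoxia at -0.13 and interferon response at 0.043. At a mean of at least 5 FPKM Wnt signalling lay at -0.036. With a pseudocount of 0.1 glycolysis lay at -0.030 and the interferon response at -0.023.

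Fry asks whether a list moves in itself, so lists whose test pointed upward relative to other genes, and whose medians as deposited lie below 0, turn by its construction; these medians as deposited were LIF/Stat3 and Bmp signalling at -0.31, formative and primed epiblast at -0.23, endoderm at -0.36, ectoderm and neural at -0.38, trophectoderm at -0.21 and feeder fibroblast at -0.047. Others were Myc family and partners at -0.31, FGF/ERK signalling at -0.33, Wnt signalling at -0.32, p53 targets at -0.32, replication-dependent histones at -0.38 and cholesterol synthesis at -0.20. Others were hypoxia at -0.36, cytoskeleton and adhesion at -0.21 and imprinted genes at -0.18.

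Leaving out 1 library makes the founder lines uneven between WT and KO in the fit without the block, so these values also hold the difference between the lines. Without single libraries, where a lone sample is assumed to vary like the other group, results whose test changed direction in at least 1 case, and the trophectoderm list, which lost its call, ranged as follows: SAGA complex -0.018 to 0.12, other acetyltransferases and deacetylases -0.092 to 0.034, LIF/Stat3 and Bmp signalling -0.054 to 0.11, formative and primed epiblast -0.41 to 0.63, endoderm -0.26 to 0.39 and ectoderm and neural -0.16 to 0.092. Other ranges were trophectoderm -0.059 to 0.45, germline -0.35 to 0.15, SR proteins -0.18 to 0.035, hnRNPs and splicing regulators -0.16 to 0.068, core spliceosome -0.11 to 0.021 and Myc family and partners -0.054 to 0.13. The ranges were nucleolar Myc targets -0.18 to 0.074, FGF/ERK signalling -0.054 to 0.17, Wnt signalling -0.090 to 0.20, p53 targets -0.16 to 0.14, replication-dependent histones -0.35 to 0.25 and glycolysis -0.38 to 0.26. Further ranges were unfolded protein response -0.13 to 0.051, hypoxia -0.42 to 0.27, interferon response -0.24 to 0.14, cytoskeleton and adhesion -0.052 to 0.19, Polycomb and DNA methylation -0.098 to -0.046 and Myc -0.96 to 0.58. Also, ranges were Mycl1 -0.51 to 0.13, Fgf15 -0.73 to 0.038 and H19 -1.46 to 0.085.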

Other observations

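Of the tests in this part, all were chosen after the data were seen. More genes were called between the founder lines than between the genotypes. With the genotype as a term and each library centred on its median, limma called 1915 genes higher and 1616 lower in line 6 than in line 4, of which 103 and 101 by at least 2-fold, where the same fit called 33 genes between the genotypes. It called 3531 in all, 1089 on values as deposited, where the prior df was infinite, 3420 with quantile normalization and 2688 among genes with a mean of at least 5 FPKM. Hfe, an iron-regulatory protein, stood at 579.5 and 414.9 FPKM in WT and KO of line 4 and at 82.0 and 39.2 FPKM in line 6 (adjusted p = 0.00422), and Lrp2, an endocytic receptor of visceral endoderm, at 2.68 and 1.80 FPKM against 12.4 and 11.7 FPKM (adjusted p = 0.00267). The list calls between the lines that follow are all lost with an estimated correlation, where the smallest adjusted p = 0.835. Genes of the formative and primed epiblast were higher in line 6, by a relative median of 1.04 (camera adjusted p = 2.63e-06), and so were endoderm genes, by 0.65 (0.000196). Glycolysis genes, hypoxia genes and replication-dependent histones were lower, at -0.60, -0.57 and -0.43 (1.11e-08, 1.74e-07 and 3.77e-05). Germline genes (-0.44, 0.000407) and ribosomal proteins (-0.12, 0.00875) were lower as well. Nucleolar Myc targets, hnRNPs, the core spliceosome and the cytoskeleton list were higher, by 0.23, 0.15, 0.13 and 0.27 (0.000124, 0.00451, 0.00451 and 0.00622). Each line is 1 derivation, so these values compare the lines at hand. The line is also the replicate number, so any difference in handling between replicates 1 and 2 cannot be told apart from the line. The Y-linked genes Ddx3y, Eif2s3y and Uty were listed at 24.2, 62.4 and 12.4 FPKM in WT of line 4 and 10.5, 35.2 and 6.60 FPKM in WT of line 6.

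Imprinted genes may differ between clones more than other genes at the same level. The median absolute change of 17 imprinted genes relative to the median gene was 0.18 in line 4 and 0.70 in line 6, against 0.09 and 0.08 for matched random lists, at the 99.1th percentile in line 4, the lower of the lines. It was 0.77 between the WT clones of the lines, against 0.22, where WT replicate 2 enters as it does in the line 6 value, and 0.40 between the KO clones, against 0.22, at the 98.8th percentile. Each clone enters 2 of these 4 values, so they are not independent. Snrpn and Snurf, which share a transcript, were at 69.6 and 84.1 FPKM in WT and 91.1 and 109.9 FPKM in KO of line 4, and at 90.7 and 109.4 FPKM in WT and 143.5 and 173.2 FPKM in KO of line 6. They passed with the block on centred values (adjusted p = 0.0469 for both), and not without the block (0.445), with the block as deposited (0.191 and 0.183) or with the block on centred values and a robust spread. Snord64 of the same locus was at 72.6 FPKM in WT and 103.9 FPKM in KO of line 4 and at 64.2 and 148.4 FPKM in line 6 (limma adjusted p = 0.445 without the block, 0.00261 with the block, 0.00189 with the block and a robust spread, and 0.0469 with the block on centred values). It, too, did not pass with the block on centred values and a robust spread. Ipw, at 0.461 and 0.655 FPKM in WT and KO of line 4 and 0.550 and 2.07 FPKM in line 6, was below the level tested. Cdkn1c was at 15.1 FPKM in WT replicate 2 and between 2.96 and 3.99 FPKM in the other libraries (adjusted p = 0.445 for KO against WT, 0.00226 with the block, 0.847 with the block on centred values).

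Among the genes the block called on centred values, 24 were Mir466, Mir467 and Mir669 entries, whose copies share sequence and in part identical values, so that they do not count as separate results. A run of 4 entries from Mir434 to Rian on chromosome 12, which is imprinted, was over 2 times each other library in WT replicate 2.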
